A study of Homo sapiens with 4 samples.

How the data were processed

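RNA from confluent Calu-3 cells was sequenced in 4 libraries: 2 from cells given a negative control siRNA (siNC) and 2 from cells given an siRNA against BACH1 (siBACH1), both delivered by lipid transfection per the labels' protocols. Libraries were made from total RNA with a TruSeq RNA kit and read from a single end. Per the submitters' processing notes, reads were processed with STAR 2.6 and the human build hg19, featureCounts 1.6.3 from Subread and DESeq2 1.22.1. The gene annotation and the strand setting are not given in the sources used here, so genes that overlap others, and near-identical family members such as the SPRR and SERPINB genes, are uncertain where reads could be shared.

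The whole series is 1 table of 26364 genes by symbol, 5165 of them at 0 in every library. Per the file headers, it holds the authors' DESeq2 log2 fold change with its standard error, the p-value and the adjusted p-value, and a column of values per library. These values per library are the authors' normalized signal: gene counts divided by 1 size factor per library. In every column 100% of values were whole multiples of a common step (within 0.0001 reads), which gives the depth: 47962660 and 44701715 reads in siNC and 48489689 and 42490452 in siBACH1. The step of siNC replicate 2 is so near 1 (0.995) that an automated check of units could not tell it from rounding, so no test of counts was run. The values there are not rounded (MAF has 20.9033), so whole counts could have been recovered. The authors' own DESeq2 columns serve as the count-based comparison. EEF1A1 took the largest share of each library, from 1.02% to 1.12%. At this depth the spread between libraries, more than sampling error, sets the precision for abundant genes, while sampling error also weighs on genes of few counts.

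Groups and replicate numbers came from the sample titles. The control libraries are described as numbers 1 and 3 by the submitters, so the replicate numbers were not taken to pair libraries. The test was limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(value + 1), over the 15622 genes with a mean normalized count of at least 10, 2 libraries against 2, with no block. Log2 changes are siBACH1 minus siNC on that scale, which understates the change of low genes. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. The procedure was tested on simulated data for siBACH1 against siNC with 15624 genes. It recovered 88% of genes simulated at a 1.5-fold change and 100% of those at 2-fold, 4-fold and 8-fold, and called 11 of 15424 unchanged genes. The genes given a change were drawn from those with a mean of at least 50, so recovery of lower genes was not measured. The simulation gave all genes and both groups the same dispersion (0.0055) and drew genes independently. In the real data the spread differed between the groups, so these rates may not hold for the real libraries.

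The 18 gene lists were written from textbook knowledge before the data were examined, and BACH1 was left out of them. They were tested with camera at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation, where 0 lists passed, and fry, where 12 passed, were run beside it. An estimated correlation is imprecise here because 4 libraries leave few residual degrees of freedom. Camera with an estimated correlation also takes its p-values at those few degrees of freedom, so a list can hardly pass. For the epithelial list the estimate (-0.032) lay below the preset value, yet its unadjusted camera p went from 2.69e-04 to 0.0549. The mesenchymal list (estimate 0.0097) went from 5.92e-05 to 0.0565. Other lists, such as ion transport (0.149), had estimates above the preset value. The rule for named genes was also fixed before the data were examined. Of the genes it names, 2 are not reported here, and counts over lists and over named genes include them. It took BACH1, CFTR and HMOX1, then, among called genes with a mean of at least 50 and separated libraries, the 10 with the largest positive and the 10 with the largest negative log2 change. From each list it took up to 4 called members with the largest absolute change, or the most abundant member where none was called. Genes named outside the rule are marked.

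Chosen after the expression values had been seen were the scan of 3' UTR sequences, prompted by the fall of TPRG1L, and the scan of symbol families, prompted by the SPRR and SERPINB genes. For the sequence scan 1 protein-coding transcript per gene (an APPRIS principal one where annotated, then the longest) of GENCODE 29 on GRCh38 was matched by symbol, and a 3' UTR of at least 50 bases was required. A 3' UTR was found for 13159 tested genes (84.2%) and for 92.7% of called genes. Log2 changes of 11798 genes with a mean of at least 50, limited to 2 in either direction, were fitted on the presence of each of 16378 sequences of 7 bases found in at least 20 genes, with 3' UTR length and GC content as covariates (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). The highest absolute z in 100 permutations of the changes was 5.71. An earlier look at genes of higher expression had already pointed to the sequences reported, so the scan is descriptive. The authors' build differs from GRCh38, so coordinates are given only for sequence matches made here.

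Alternatives tried were limma without the trend, centring of the libraries on their median, other filters on low values, other pseudocounts, the replicate number as a block, leaving out each library, stricter thresholds and the authors' deposited comparison. For the lists, an estimated correlation and fry were tried. Added after seeing the data were the lists without HMOX1 and a subset of genes without a seed match. In that subset the calls of the main fit were counted and the list test was run again. The BACH1 and control siRNA sequences are not given in the sources used here.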

Results

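Gene expression was measured by single-end RNA sequencing of Calu-3 cells, an established human lung adenocarcinoma line with airway epithelial features. The cells had been transfected with a small interfering RNA (siRNA) against BACH1, a heme-binding transcription factor that represses antioxidant genes, or with a negative control siRNA. There were 4 libraries, 2 siNC (control) and 2 siBACH1, and the series title names CFTR, the epithelial chloride channel mutated in cystic fibrosis, as the gene of interest. The libraries held 47962660 and 44701715 assigned reads in siNC and 48489689 and 42490452 in siBACH1, as recovered from the step between values. At that depth the spread between libraries, more than counting error, limited the precision for abundant genes. Genes of few counts were less precise. The SE of the log2 change was 0.33 for MAF, with a mean of 73 normalized counts, against 0.062 for ATP5B, with a mean of 47851. The chi-square per degree of freedom was 25.3 between the siNC libraries and 7.11 between the siBACH1 libraries, so both pairs differed by more than sampling noise. The median absolute log2 difference between libraries of a group was 0.15 in siNC and 0.09 in siBACH1. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

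BACH1, the siRNA target, was lower in both siBACH1 libraries. It had 2188 and 2611 normalized counts in siNC against 532 and 542 in siBACH1, a log2 change of -2.15 (SE 0.11, limma adjusted p = 7.09e-05), which is 4.44-fold lower. HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1, made the largest change of any named gene. It went from 342 and 269 normalized counts in siNC to 26026 and 25381 in siBACH1, 84.5-fold higher (log2 change 6.40, SE 0.11, limma adjusted p = 5.92e-08). The authors' deposited table gives a log2 change of -2.16 for BACH1 and 6.39 for HMOX1.

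CFTR did not pass the test. Its normalized counts were 7389 and 10199 in siNC and 8145 and 9242 in siBACH1, so both siBACH1 values lay between the siNC values. The log2 change was -0.00087, with a 95% interval from -0.32 to 0.32 and a limma adjusted p of 0.998. The authors' deposited table has -0.017 with an adjusted p of 0.970. The sign depended on which libraries were kept, in both groups. The log2 change was -0.23 without siNC replicate 1 and 0.23 without siNC replicate 2. It was 0.09 without siBACH1 replicate 1 and -0.09 without siBACH1 replicate 2. The opposite signs without a siNC library follow from siBACH1 values that lie between the siNC values. With 1 library left in a group, the residual spread came from the pair of the other group alone, so p-values of these fits are left out. Centring each library on its median gave 0.0088 (limma adjusted p = 0.976), and without the mean-variance trend the limma adjusted p was 0.999.

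**Figure D1:**
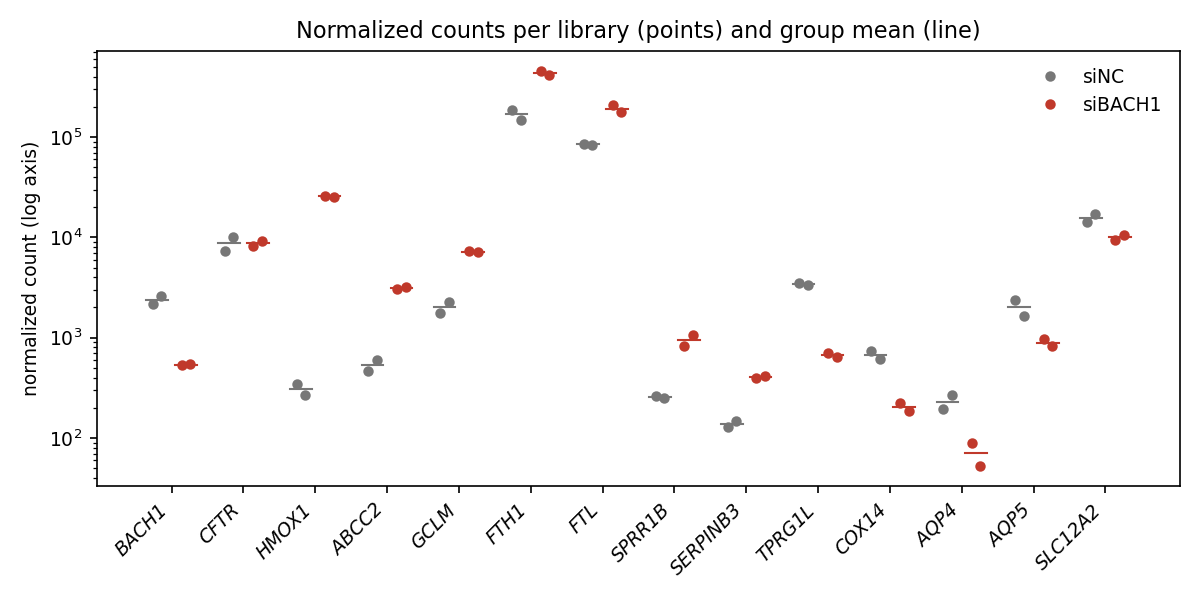
Normalized counts (log axis) of 14 genes in each library; grey points are siNC, red points siBACH1, and lines are group means. BACH1 falls from 2188 and 2611 to 532 and 542, HMOX1 rises from 342 and 269 to 26026 and 25381, and the CFTR points of both groups overlap.

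Across the transcriptome, 890 genes were higher and 572 lower in siBACH1 among 15622 tested, and 96 and 94 of these changed at least 2-fold. Among called genes with a mean of at least 50 normalized counts, the largest increase after HMOX1 was in ABCC2, an organic anion export pump (log2 change 2.56, 5.90-fold). MAF, a bZIP transcription factor, followed (1.89, or 1.39 without siNC replicate 2), then SPRR1B, a cornified envelope precursor (1.85). GCLM, the modifier subunit of glutamate-cysteine ligase, rose by 1.84, NAV3 by 1.66, SUN3 by 1.63, SPRR2A by 1.59 and SERPINB3 by 1.56, and ZBED2 was 3.03-fold higher. The largest decrease was in TPRG1L, which fell by 2.34 on the log2 scale, from 3423 ± 143 to 675 ± 38.8 normalized counts (SD, n = 2). Its 95% interval (-2.54 to -2.14) overlapped that of BACH1 (-2.40 to -1.91). ALDH1L1, a folate-metabolizing dehydrogenase, fell by 1.94, MGP, the matrix Gla protein, by 1.89, and FCGBP, a mucus protein, by 1.82. COX14, an assembly factor of cytochrome c oxidase, fell by 1.73, AQP4 by 1.72, SCTR, the secretin receptor, by 1.59, SERPINA6 by 1.56 and CCDC51 by 1.51.

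In all 1462 called genes the libraries of the groups did not overlap. This was so for 55.5% of all tested genes, against 33.3% by chance. The authors' deposited table calls 979 genes higher and 517 lower at the same threshold, of which 850 and 467 were shared with the refit, and 0 genes were called in opposite directions. The counts depended on single libraries. They were 295 higher and 210 lower without siBACH1 replicate 1, 221 and 131 without siBACH1 replicate 2, 2337 and 1559 without siNC replicate 1, and 2573 and 1928 without siNC replicate 2. Without the mean-variance trend in limma, 62 and 39 genes passed.

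**Figure D2:**
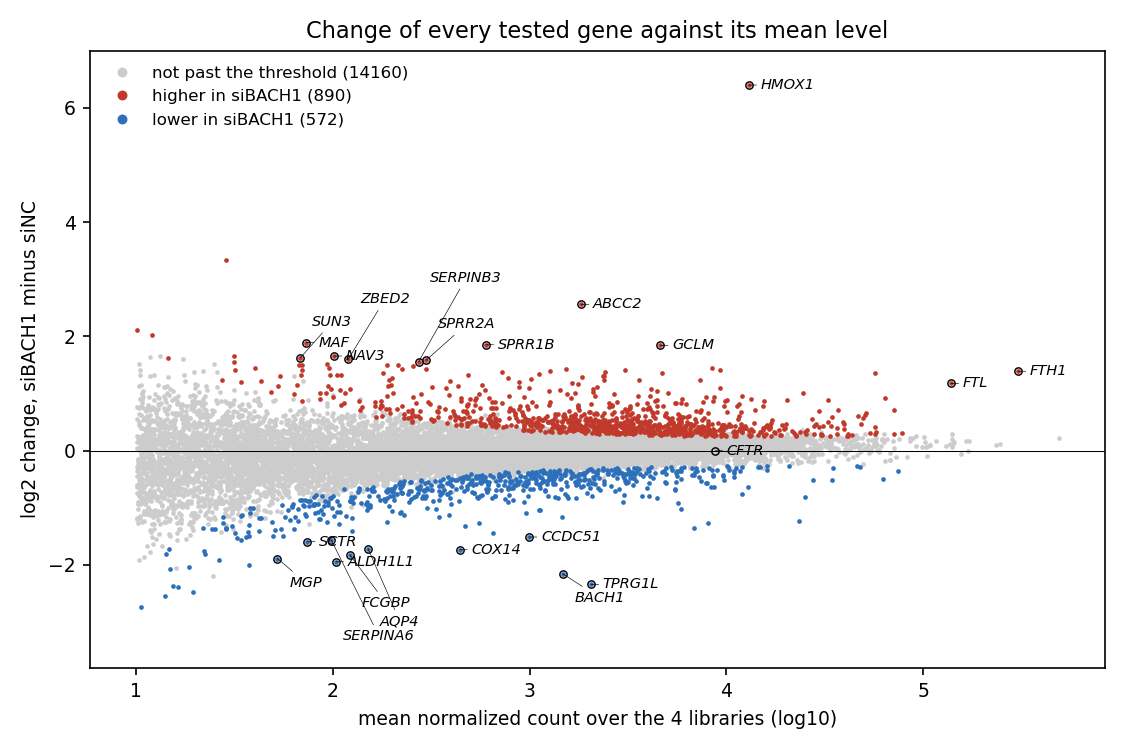
Log2 change (siBACH1 minus siNC) of each tested gene against the log10 of its mean normalized count over the 4 libraries; red genes are higher (890), blue genes lower (572), grey genes did not pass, and circled genes are named. HMOX1 stands at 6.40, far above every other labelled gene, while TPRG1L and BACH1 are the lowest labelled genes at -2.34 and -2.15.

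Short sequence matches in 3' untranslated regions (3' UTRs) went with the changes, in a scan chosen after the expression values had been seen. In a model with 3' UTR length and GC content, genes with GAATCGT in the 3' UTR were lower in siBACH1 (log2 coefficient -0.21, SE 0.02, 224 genes) and genes with GCAACCA were higher (0.13, SE 0.01, 761 genes). Of the 526 lower genes with a searched 3' UTR, 58 (11.0%) held GAATCGT or AATCGTA, against 2.84% of other genes. Of the 830 higher genes searched, 364 (43.9%) held the core GCAACC, against 18.8% of other genes. TPRG1L, COX14 and CCDC51 each hold GAATCGT followed by A in the 3' UTR, in GRCh38 with GENCODE 29 annotation at chromosome 1, 3628769 to 3628775 (exon 5), chromosome 12, 50120393 to 50120399 (exon 2), and chromosome 3, 48432342 to 48432348 (exon 4, minus strand). BACH1 holds GAATCGT followed by A in its coding sequence, at chromosome 21, 29321465 to 29321471 (exon 2). HMOX1, ABCC2, GCLM, MAF, SPRR1B and CFTR hold neither GAATCGT nor GCAACC in the 3' UTR, and SERPINB3 holds GCAACC.

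Most NRF2-driven antioxidant genes were higher. Of 35 members tested, 24 were higher, 0 lower and 11 did not pass over all genes, and 27 were higher and 1 lower adjusted over the list alone (median log2 change 0.39, camera adjusted p = 6.09e-18; adjusted p = 0.308 with an estimated correlation). HMOX1, ABCC2 and GCLM led the list, and FTH1, the ferritin heavy chain, rose from 168313 ± 27744 to 438871 ± 30305 normalized counts (SD, n = 2; log2 change 1.39, SE 0.11). The heme and iron genes, which share HMOX1, FTL and FTH1 with that list, had 6 of 16 members higher and 0 lower, or 7 and 0 adjusted over the list alone (median 0.17, camera adjusted p = 0.00140; adjusted p = 0.319 with an estimated correlation). FTL, the ferritin light chain, rose by 1.18 and ABCB6, a porphyrin transporter, by 0.52. Without HMOX1, a setting chosen after seeing the data, both lists still passed, with camera adjusted p of 3.07e-16 and 0.0162, where the alternatives ranged up to 0.308 and 0.319. Among 12 regulators of the BACH1 and NRF2 axis only the small MAF gene MAFG passed (0.39, SE 0.08, with GCAACC in the 3' UTR), or 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.827). NFE2L2, which encodes NRF2 and was named after its value was seen, had a log2 change of 0.12 (adjusted p = 0.399).

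Of 21 airway ion and fluid transport genes tested, 10 were lower, 0 higher and 11 did not pass, or 12 lower and 2 higher adjusted over the list alone (median -0.39, or -0.25 without siNC replicate 1, camera adjusted p = 2.52e-05; adjusted p = 0.319 with an estimated correlation). The water channel AQP4 had 231 ± 49.4 normalized counts in siNC and 71.0 ± 26.4 in siBACH1 (SD, n = 2; log2 change -1.72, SE 0.27), and AQP5 went from 2009.7 ± 519 to 892 ± 101 (-1.15, SE 0.16). KCNE3, a potassium channel subunit, fell by 0.72 (it holds 2 GCAACC matches in the 3' UTR), and SLC12A2, the basolateral sodium-potassium-chloride cotransporter, by 0.64. Of 23 factors reported to act at the CFTR locus, 2 were higher and 0 lower by either adjustment, including adjusted over the list alone (median 0.13, camera adjusted p = 0.00855; adjusted p = 0.308 with an estimated correlation). These were ZBTB7A (0.49, SE 0.09, with GCAACC in the 3' UTR) and the epithelial factor ELF3 (0.38, SE 0.07).

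Of 29 inflammatory cytokine and chemokine genes, 12 were higher, 1 lower and 16 did not pass, or 14 and 1 adjusted over the list alone (median 0.34, camera adjusted p = 1.71e-05; adjusted p = 0.319 with an estimated correlation). The cytokine IL1B rose by 1.27, from 116 ± 0.801 to 281 ± 13.8 normalized counts (SD, n = 2), and PTGS2, the inducible cyclooxygenase, by 1.12. The mitochondrial superoxide dismutase SOD2 rose by 0.79 and the chemokine CCL28 by 0.60. IL1B, SOD2 and CCL28 hold GCAACC in the 3' UTR and PTGS2 does not, and among searched genes without GAATCGT, AATCGTA or GCAACC, a subset chosen after seeing the data, the median of the list was 0.19. The lower member was ICAM1 (-0.44), named after its value was seen. Of 19 mesenchymal and invasion genes, 7 were higher and 1 lower, or 9 and 1 adjusted over the list alone (median 0.30, camera adjusted p = 2.67e-04; adjusted p = 0.308 with an estimated correlation). Fibronectin (FN1) rose by 0.82 and the collagenase MMP1 by 0.66. These are secreted or matrix proteins, and the lower member was VIM, the intermediate filament vimentin (-0.31), named after its value was seen.

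Epithelial junction and keratin genes had 6 of 27 members higher and 0 lower, or 8 and 0 adjusted over the list alone (median 0.12, or 0.23 without siNC replicate 1, camera adjusted p = 9.70e-04; adjusted p = 0.308 with an estimated correlation). The transcription factor OVOL1 rose by 0.54, claudin 7 (CLDN7) by 0.40, occludin (OCLN) by 0.40 and the lipid enzyme CDS1 by 0.40, and all of these but CLDN7 hold GCAACC in the 3' UTR. Hypoxia genes had 4 of 20 higher and 0 lower, or 9 and 0 adjusted over the list alone (median 0.19, camera adjusted p = 0.00616; adjusted p = 0.308 with an estimated correlation). These were carbonic anhydrase CA9 (0.86, or 0.56 without siNC replicate 2), KDM4B (0.43) and EGLN1 (0.29), both with GCAACC, and P4HA2 (0.26). The integrated stress and unfolded protein response list had 3 of 28 higher and 1 lower, or 9 and 3 adjusted over the list alone (median 0.12, camera adjusted p = 0.0142; adjusted p = 0.319 with an estimated correlation). The chaperone DNAJB9, which holds GCAACC, rose by 1.01, the phosphatase subunit PPP1R15A by 0.47 and ATF4 by 0.36, while the serine synthesis enzyme PSAT1 fell by 0.34. Without siNC replicate 2 the camera adjusted p of this list was 0.0606, and among searched genes without GAATCGT, AATCGTA or GCAACC it was 0.0985, in a range from 0.00423 to 0.319 over all alternatives.

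The other 9 lists did not pass camera. In the secretory airway list 4 of 19 were higher and 5 lower, the same numbers as adjusted over the list alone (camera adjusted p = 0.472). The membrane mucins MUC16 and MUC4 were 2.84-fold and 2.39-fold higher, and MUC20 (0.84) and SLPI (0.46), named after their values were seen, were also higher. PIGR, the polymeric immunoglobulin receptor, fell by 1.13 and the secretory cell transcription factor SPDEF by 1.09 (by 0.70 without siNC replicate 1), though both hold GCAACC. MUC5B (-0.55), LYZ (-0.35, though with GCAACC) and AGR2 (-0.29), named after their values were seen, were lower too. Among 35 replication and mitosis genes, RRM2 (-0.68), KIF23 (-0.47, or -0.30 without siNC replicate 2) and AURKA (-0.40, with GAATCGT in the 3' UTR) fell and TTK (0.56, with GCAACC) rose, or 4 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.123). This list passed as lower without siNC replicate 1 (median -0.19) and without siBACH1 replicate 2 (median -0.14). Its estimated correlation between genes was 0.633, against the preset 0.01, so the preset test may be too lenient for it. With the estimated correlation its camera adjusted p was 0.848, the highest over the alternatives. Of 30 interferon-stimulated genes, OAS1 (0.43), OAS2 (0.42) and OAS3 (0.31, with GCAACC, named after its value was seen) were higher and XAF1 (-0.88, though with GCAACC) and IFI44 (-0.33) lower, or 3 higher and 6 lower adjusted over the list alone. Their median (0.03, or -0.05 without siNC replicate 2) was positive and their mean (-0.05) and test negative (camera adjusted p = 0.761).

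In glycolysis, lactate dehydrogenase LDHA (0.71) and the glucose transporter SLC2A1 (0.44), both with GCAACC, rose and hexokinase HK1 fell by 0.36, the same 2 and 1 of 21 as adjusted over the list alone (camera adjusted p = 0.143). The p53 list had PHLDA3 (0.45, or 0.27 without siNC replicate 2, with GCAACC) and BAX (0.35) higher of 23, or 6 higher adjusted over the list alone (camera adjusted p = 0.0860). In sterol synthesis only MSMO1 (0.40, with GCAACC) of 24 was higher, by either adjustment, including adjusted over the list alone (camera adjusted p = 0.442), and without siNC replicate 2 that list passed as lower (camera adjusted p = 0.0183, highest over the alternatives 0.870). Of 52 respiratory chain genes 0 passed in limma, also adjusted over the list alone (camera adjusted p = 0.820), 3 had an unadjusted p under 0.05, and the authors' deposited table calls 0. The most abundant, ATP5B, had 48102 ± 788 normalized counts in siNC and 47599.7 ± 38.5 in siBACH1 (SD, n = 2). Markers of other cell types, 7 of which were expressed enough to test, gave 0 limma calls with either adjustment, including adjusted over the list alone (camera adjusted p = 0.614). Of these, 1 had an unadjusted p under 0.05 and the authors' deposited table calls 0, and KRT15, the most abundant, had 502 ± 43.8 and 533 ± 28.6 normalized counts. Leaving out siBACH1 replicate 1 ended the call of 24 named genes and leaving out replicate 2 that of 32, and none of these changed direction.

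**Figure D3:**
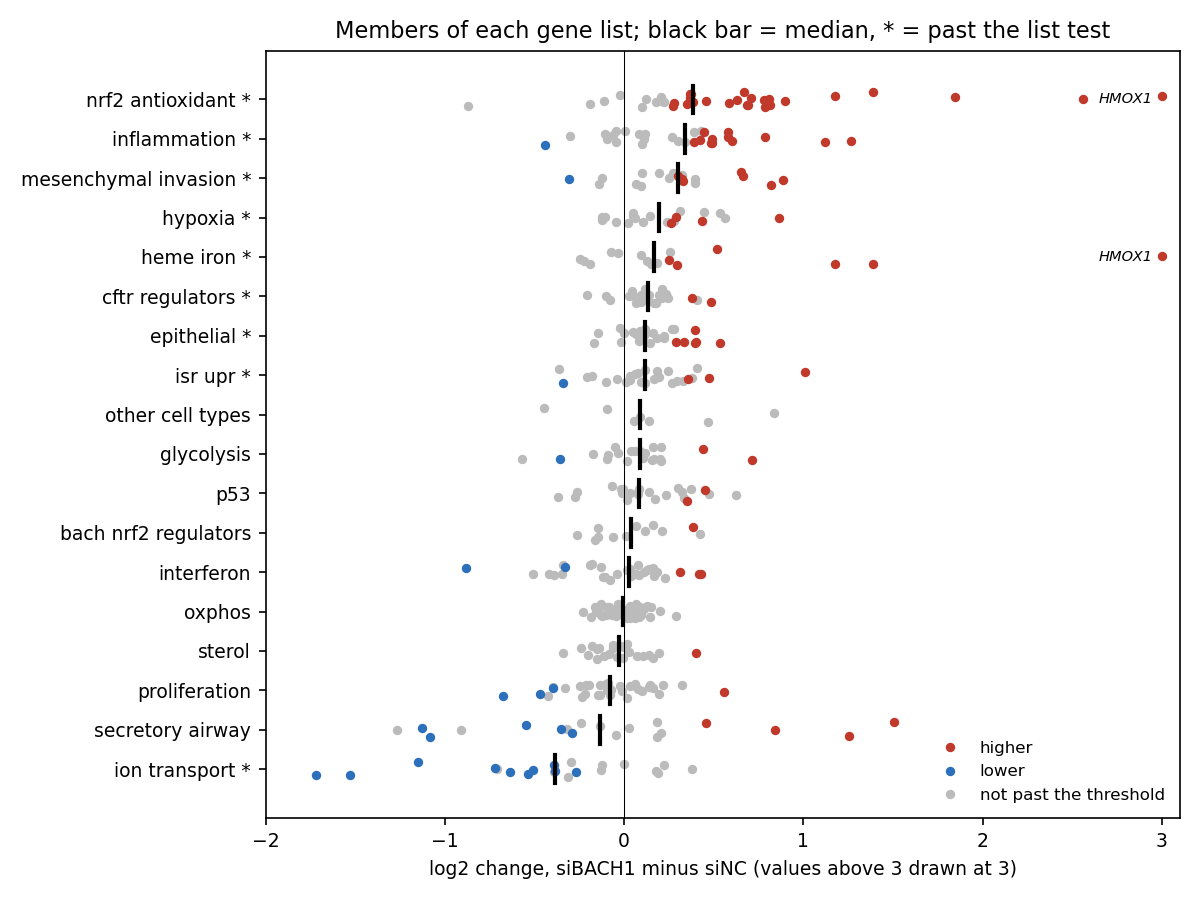
Log2 change (siBACH1 minus siNC) of each tested member of the 18 gene lists; points are genes (red higher, blue lower, grey not past the threshold), black bars are list medians, stars mark the 9 lists past camera at the preset correlation, and HMOX1 at 6.40 is drawn at 3. The NRF2 antioxidant list has the highest median (0.39) and the ion transport list the lowest (-0.39).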

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

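BACH1 stayed lower and past the threshold under all 12 alternatives (log2 change -2.28 to -2.02), as did HMOX1 higher (6.23 to 6.57). CFTR was past the threshold only without a siNC library, where the residual spread comes from the siBACH1 pair alone. It ranged from -0.23 to 0.23 with 1 library left out. Both siBACH1 values lie between the siNC values, so the opposite signs follow from which siNC library is kept. With the libraries centred on their median the log2 change of CFTR was 0.0088. ATP5B, not past in any fit, ranged from -0.032 to 0.0017 with 1 library left out. The number of genes called depended on the estimate of the spread. Without the mean-variance trend 62 genes were higher and 39 lower (55 and 21 shared with the authors' deposited table). An adjusted p below 0.01 gave 300 and 140, and a change of at least 2-fold 96 and 94. Leaving out 1 library gave 221 to 2573 higher and 131 to 1928 lower (221 to 979 and 116 to 516 shared with the authors' deposited table), fewer without a siBACH1 library and more without a siNC library. A lone library is assumed there to vary like the other group, and the siBACH1 pair had the smaller spread. Of the 1462 called genes, 481 kept their call without siBACH1 replicate 1 and 345 without siBACH1 replicate 2. With the replicate number as a replicate block, 2096 were higher and 1549 lower. The control libraries are described as 1 and 3, only 2 pairs exist and deviations of same-numbered libraries correlated at 0.142, so the numbers share no stated pairing. Centring, other filters and other pseudocounts kept both counts within 1.5 times. Among searched genes with no seed match, a subset chosen after seeing the data, 462 of 10228 were higher and 390 lower. These are calls of the main fit and not of a new one.

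With an estimated correlation 0 of the 18 lists passed, against 9 at the preset one, and 1 had an unadjusted p under 0.05. That test has few degrees of freedom here, so it cannot tell whether correlation between genes accounts for the loss. With fry 12 passed. The 9 lists kept their direction throughout. Apart from the estimated correlation, only the stress response list lost its call, without siNC replicate 2 and among genes with no seed match. The proliferation list passed as lower under the block and without siNC replicate 1 or siBACH1 replicate 2, and the sterol list without siNC replicate 2. The estimated correlations of these lists were 0.633 and 0.449, so the preset 0.01 may be too lenient for them. The cause was not tested. Among named genes, 49 lost their call without the trend, 8 without the filter on low values, which tests more genes, 2 after centring, 2 in the authors' deposited table and 1 under the stricter filter. The values are already normalized by the authors, so normalization as deposited is the reported fit, and library totals alone apply only to counts and were not run.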

Other observations

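Tests chosen only after the result was seen were the scan of symbol families, the scan of 3' UTR sequences, the subset without seed matches and the lists without HMOX1. The comparison of longer with shorter GCAACC matches and both comparisons with other sequences of the same bases were also chosen then.

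Several gene families, some sharing genes with the fixed lists, held more called members than chance would give. They were found among 510 families of at least 5 tested genes sharing the letters of their symbol (1020 one-sided Fisher's exact tests, both directions). Members named here were chosen after their values were seen. The SPRR genes, precursors of the cornified envelope of squamous epithelium, had 8 of 10 members higher and 0 lower (median log2 change 1.51, adjusted p = 2.23e-06), among them SPRR3, which went from 2638 ± 89.6 to 5586 ± 11.2 normalized counts (SD, n = 2). The SERPINB genes, intracellular protease inhibitors, had 7 of 10 higher and 0 lower (median 0.84, adjusted p = 6.68e-05), and SERPINB2 rose by 1.46 while SERPINB4, which holds GCAACC, was 2.84-fold higher. The secreted SERPINA genes went the other way, with 4 of 5 lower (median -0.49, adjusted p = 0.00220), including the acute-phase inhibitors SERPINA3 (-0.49) and SERPINA1 (-0.43, though with GCAACC). Genes within a family lie near each other in sequence and often in the genome, so they are not independent, and closely similar members may share reads. Of 8 SPRR genes with a searched 3' UTR, 7 were higher and 0 held GCAACC, while 4 of the 7 higher SERPINB genes held it.

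Aldo-keto reductase genes had 6 of 12 members higher (adjusted p = 0.00471), led by AKR1B1 (1.09), which was not in the NRF2 list and holds GCAACC, while the other 5 hold none. Of those 5, AKR1C1, AKR1C2 and AKR1C3 are in the NRF2 list. Genes with symbols of the IL group, mostly interleukins and their receptors, went both ways, with 11 of 45 higher and 4 lower (adjusted p for higher = 0.00557). Among the higher genes, IL1A, IL1B, IL6, IL18 and IL32 are also in the inflammatory list. IL6R, with 2 GCAACC matches, rose by 1.12 (4 of the 11 higher genes hold one), while IL27RA (-1.06), IL11RA (-1.07), IL33 (-0.94) and IL17D (-0.99) fell. Myosin genes had 7 of 21 higher (adjusted p = 0.0159), led by MYO5C (0.82), and 2 of the 7, MYO5C among them, hold GCAACC. All 7 MTRNR2L genes, near-identical copies of mitochondrial ribosomal RNA sequence, were higher (median 0.41, adjusted p = 1.94e-06), and reads cannot be assigned among them; 2 of the 5 searched hold GCAACC. SLC26A9, an airway chloride channel in the ion transport list with too low a mean for the naming rule, fell by 1.53 (adjusted p = 0.0172).

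The falls of TPRG1L, COX14 and CCDC51 go with the sequence GAATCGT, of 16378 sequences of 7 bases the one most strongly linked to lower expression (z = -10.8, against a highest absolute z of 5.71 in 100 permutations) and the leading one in each random part when the genes were divided into 2 parts. A hypothesis is that the BACH1 siRNA repressed these transcripts through its seed region, the short stretch near its 5' end. The BACH1 transcript held 1 match of GAATCGT, which a full-length target needs to hold and which 4.52% of all expressed transcripts hold, or 6.52% of the 2072 within 20% of its length of 5769 bases. The strongest of 612 other orders of the same bases had a coefficient of -0.060, against -0.21. Orders sharing 5 bases in a row with the site were left out, among them TGAATCG (-0.15), the site moved by 1 base. The scan had already picked GAATCGT as the leading sequence among lower genes. Weaker other orders were therefore close to fixed, and the comparison decides nothing about base composition. For any single gene, seed pairing and loss of BACH1 both stay open, because no other BACH1 siRNA and no siRNA sequence were used here.

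Genes that rose were enriched for GCAACC, and a hypothesis is that the control siRNA repressed them in the siNC libraries. Genes with the 8-base match AGCAACCA lay 0.0998 above genes with only the 6-base core (95% bootstrap interval 0.0677 to 0.15, resampling genes and not libraries). The scan had already picked both 7-base parts of that match as the leading sequences among higher genes, so a positive difference was close to fixed and decides nothing. The strongest of 125 other orders of the bases of AGCAACC had a coefficient of 0.056, against 0.12, and 0 of them came within 2 standard errors. That comparison was changed after its first result: GCAACCA, the same site moved by 1 base, had at first counted as another order and matched the effect, and orders sharing 5 bases in a row with the site were then left out. Later the strongest other order was taken by coefficient and no longer by z, for both sequences, and both sites stayed ahead of it. AGCAACC too had been picked from the top of the scan, so this comparison decides nothing about base composition either. A small RNA of the cells that lost activity in siBACH1, and BACH1 itself acting on such genes, stay open, as no untransfected cells were analysed here. The hypothesis would bear on IL1B, SOD2, LDHA and DNAJB9, of which SOD2 and DNAJB9 hold only the 6-base core. Genes with the 8-base match had a median log2 change of 0.14. With only the core it was 0.040, and with no match 0.0046. IL1B (1.27), DNAJB9 (1.01), SOD2 (0.79) and LDHA (0.71) rose far more than these medians.

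The rise of the NRF2 antioxidant list may in principle come from the control siRNA pairing with GCAACC in the 3' UTRs of its members. The values argue against that route only. Effects of the control siRNA on these members through coding sequence or through other genes were not tested. Over all scanned genes, the 527 with AGCAACCA in the coding sequence had a median log2 change of 0.067. It was 0.0048 for genes with no GCAACC there. These medians were not adjusted for matches in the 3' UTR. The 28 searched members without GCAACC had a median log2 change of 0.415 (95% bootstrap interval 0.246 to 0.732), and 19 of them were higher. The bootstrap resampled genes as if independent, so the interval does not measure the spread between libraries. The 7 members with GCAACC had a median of 0.39. HMOX1, ABCC2, GCLM, FTH1 and FTL hold no match in the 3' UTR. Loss of repression by BACH1 stays open as the biological explanation, untested by a second siRNA or by binding data here.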
